A study of Mus musculus with 6 samples.

How the data were processed

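Liver RNA of 6 male mice was measured, 3 wild type (WT) and 3 with a whole-body knockout (KO) of Gpr146, a G protein-coupled receptor. Per the labels, the animals were littermates on a C57BL/6J background, aged 24 weeks, and were fasted for 16 hours and refed for 6 hours before the livers were taken. Per the labels' protocols, RNA was extracted with Trizol and labelled as cRNA for a whole-transcript Affymetrix array, on which probes along a gene are summarised to 1 value per probe set. The authors deposited 1 table of log2 values with 41345 probe sets and 1 column per mouse. The summary and normalization methods behind the deposited log2 values are not given in the sources used here. The log2 scale was read from the values: their maxima of 12.1 to 12.2 exceed 11.1, the natural log of the highest reading of a 16-bit scanner. All 6 columns were matched to a mouse by name, and 0 columns were left unmapped.

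Genes were named from the platform annotation, with symbols updated through Entrez numbers to a reference gene table of the GRCm38.p6 assembly. Of the probe sets, 23521 carried 1 gene symbol, 1814 carried several and 16010 had no gene listed; 23328 of the single-gene probe sets had their number in the reference. Probe sets with several symbols or none were left out. For 1082 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was used, which left 22180 genes. The 11090 genes in the upper 50% of mean signal, at or above a log2 value of 2.99, were tested. The build behind the array's design is not given in the sources used here, so no coordinates are printed and the reference was used for names and gene order.

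KO and WT were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate) on the deposited log2 values, with Benjamini-Hochberg adjustment at 0.05. Differences are KO minus WT on the log2 scale. Single values were also compared by an exact two-sided permutation test, whose smallest possible p for 3 against 3 is 0.1. Background on an array compresses folds of weak signals, and the number of mice limits the precision: the median standard error of a log2 difference was 0.11.

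Before the data were examined, 32 gene lists were fixed from general knowledge. The 5 primary lists were cholesterol biosynthesis, other SREBP2 target genes, fatty acid synthesis, lipoprotein assembly and secretion, and ERK output with immediate early genes. The others covered bile acids, LXR targets, gluconeogenesis and fasting, glycolysis and feeding, fatty acid oxidation, cAMP and CREB response, circadian clock, acute phase, interferon response, male-biased and female-biased liver genes, unfolded protein response, xenobiotic metabolism, periportal and pericentral hepatocytes, cell cycle, oxidative phosphorylation, and markers of Kupffer, sinusoidal endothelial, stellate, bile duct, T and NK, B and plasma, neutrophil and monocyte, erythroid, fat and pancreatic acinar cells. Lists were tested with camera (preset inter-gene correlation of 0.01), adjusted over the 32 lists, with an estimated correlation and fry as alternatives. Camera compares a list with all other tested genes, not with 0. The median difference of all genes tested was 0.027, so camera can point down for a list whose own mean is near 0. Members were also adjusted over the list alone. Some listed genes, including 4 of the cholesterol list and 2 of the other SREBP2 targets, had no single-gene probe set in the table used and were not analysed here. Genes within 5 Mb of Gpr146 in the reference formed a further list.

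The rule for named genes, also fixed before the data were examined, took Gpr146; up to 15 genes per direction past the threshold with every KO value on one side of every WT value; where fewer than 20 genes passed, the genes of smallest unadjusted p with such separation, up to 10 per direction; every member of the cholesterol and other SREBP2 lists; in each other list up to 4 members past the threshold over all genes or over the list alone, otherwise the 2 of smallest p; and Alb and Xist as tissue and sex checks. Placeholder symbols such as those ending in Rik were outside the rule. Genes named beyond it are said to be chosen after their values were seen.

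The gene fit and the list test were tested on data simulated from the real gene means and SDs, 5 runs with 200 changed genes among 11090. At a fold of 1.5 limma called 56.1% of 335 changed genes, at 2 86.0% of 335 and at 4 97.9% of 330. Of all calls, 4.88% were false. With 200 changed genes, the adjustment passes larger unadjusted p-values than where few genes change. The real comparison called 4 genes, so these shares do not give its chance of calling such folds. Camera called 5 of 5 shifted and 0 of 5 unshifted lists of 17 genes; the simulated genes were uncorrelated. Alternatives covered the signal filter (none, or the upper 25%), the mean of a gene's probe sets, quantile normalization, median centring, trend and robust options, array weights, probe sets with several symbols, a pseudocount of 16 on the linear scale, the replicate number as a block, each mouse left out, and the list test. After the data were seen, every probe set without a filter and the nearest 50 genes on each side of Gpr146 were added, as was the count of members past the threshold over their list alone with each mouse left out. Figures were drawn with matplotlib in Python.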

Results

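The data are 6 liver transcriptomes of refed male mice, 3 WT and 3 Gpr146 KO, each measured on 1 array. Array medians lay between 2.67 and 2.73 on the log2 scale, and any 2 arrays correlated at 0.983 to 0.988 over all probe sets. No 2 columns were copies of each other. Alb, the main liver plasma protein gene, was at 11.92 ± 0.02 in WT and 11.91 ± 0.01 in KO (mean ± SD, n = 3 each). Xist, expressed in females, was at 2.15 ± 0.16 and 2.15 ± 0.05, below the signal filter.

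The comparison of KO with WT asks how the liver transcriptome differs after refeeding when this receptor is missing. Gpr146 itself measured 5.96, 5.56 and 5.65 in WT mice 1 to 3 and 4.61, 4.28 and 3.87 in KO mice 1 to 3, so every KO mouse lay below every WT mouse. The difference was -1.47 ± 0.19 (SE), a signal 2.77-fold higher in WT, with limma's adjusted p at 0.0702 and an exact permutation p of 0.1, the smallest that 3 against 3 allows. It therefore did not pass the threshold; the adjusted p was 0.0204 after median centring, 0.0272 with trend and robust options and 0.0269 without WT mouse 3, and reached 0.270 among the other alternatives; the difference was -0.97 with the pseudocount. Which part of the gene was deleted, and whether these probes lie inside it, is not given in the sources used here, so the remaining KO signal does not measure residual receptor.

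Across the 11090 genes tested, 4 changed at an adjusted p under 0.05 in limma. C130050O18Rik, an uncharacterised protein-coding gene beside Gpr146, rose by 2.56 ± 0.14 (SE), from 3.31 ± 0.07 to 5.87 ± 0.27 (SD, n = 3 each), which is 5.89-fold (limma adjusted p = 0.000348). D930048N14Rik rose by 1.34 ± 0.14 and Map2k6, a kinase that activates p38, by 0.98 ± 0.11. Rhbg, an ammonium transporter of the Rh family, fell by 1.12 ± 0.12, and these 3 shared an adjusted p of 0.0315. C130050O18Rik and D930048N14Rik are outside the naming rule and were named after their values were seen. C130050O18Rik passed with each mouse left out in turn (adjusted p at most 0.00535) and, at 1.52, with the pseudocount (0.00777). Map2k6, Rhbg and D930048N14Rik passed without WT mouse 3 and lost the call when any other single mouse was left out; all 3 lost it with the pseudocount (adjusted p = 0.0935 each), and Map2k6, at 0.92, also with quantile normalization (0.0772). Without WT mouse 3, 51 genes passed, 11 higher and 40 lower, and these included all 4.

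**Figure D1:**
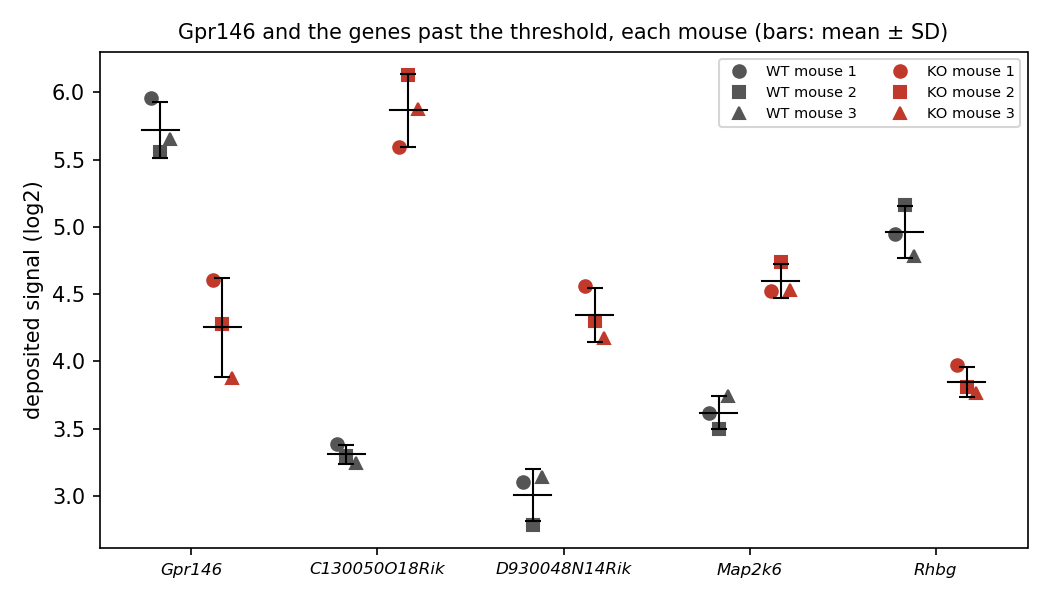
Deposited log2 signal of Gpr146 and of the 4 genes past the threshold in each of the 3 WT (grey) and 3 KO (red) livers, with mean ± SD as bars. The KO values of C130050O18Rik centre on 5.87 against 3.31 in WT, and in all 5 genes the genotypes do not overlap.

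In all, 1013 genes, these 4 included, had an unadjusted p under 0.05, 683 higher and 330 lower in KO, where chance gives about 554. Quantile normalization turned that balance, to 494 higher and 584 lower, and median centring gave 508 and 355. KO and WT did not overlap in 1640 genes, 14.8% against the 10% that chance gives. Among the genes of smallest p that did not pass, Got1, the cytosolic aspartate aminotransferase, differed by -0.85 ± 0.12 (SE; adjusted p = 0.129), Slc27a1, a fatty acid transporter, by -0.89 ± 0.15 and Trp53inp1 by -0.81 ± 0.13. Gpx6, Defb15 and Il1a were at -0.71, -0.58 and -0.78, and at -0.33, -0.22 and -0.27 with the pseudocount. On the other side Arrdc3, an arrestin-domain gene, was at 1.12 ± 0.20, Tk1, thymidine kinase, at 0.95 ± 0.16 and Zfp354a at 0.71 ± 0.10. Unc13b, Il15ra, Phf11c, Shroom1, Inhba, Erbb3 and Slc22a28 lay between 0.51 and 0.73. Adjusted p-values of these genes ran from 0.122 to 0.245. Without WT mouse 3, Got1, Trp53inp1, Arrdc3, Zfp354a and Unc13b passed (limma adjusted p = 0.0210, 0.0210, 0.0187, 0.0187 and 0.0476).

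Genes of cholesterol synthesis were lower as a group in KO livers. All 17 members tested had a negative difference, with a mean of -0.55, and the list fell in camera (adjusted p = 8.24e-17). With an estimated correlation the adjusted p was 0.586 (unadjusted p = 0.0395), and with fry 0.345, so the call is lost there. Adjusted over the list alone, 12 members fell; over all genes 0 did, and 13 had an unadjusted limma p under 0.05. Hsd17b7, a sterol ketoreductase, fell by 0.96 ± 0.18 (SE), Hmgcs1, the synthase ahead of the mevalonate step, by 0.94 ± 0.26, Sqle, squalene epoxidase, by 0.83 ± 0.29 and Msmo1 by 0.83 ± 0.21, all adjusted over the list alone. Pmvk, Mvd, Lss, Cyp51, Fdft1, Mvk, Dhcr7 and Lbr fell by 0.73, 0.73, 0.66, 0.54, 0.52, 0.52, 0.32 and 0.27 in the same adjustment. Fdps, Nsdhl, Tm7sf2, Sc5d and Ebp did not pass with all 6 mice, at -0.49, -0.45, -0.24, -0.20 and -0.09. Without KO mouse 3, Hmgcs1, Msmo1, Mvd, Sqle, Fdft1 and Dhcr7 were at -0.58, -0.54, -0.48, -0.44, -0.29 and -0.21, and Fdps, Nsdhl and Tm7sf2 at -0.27, -0.22 and -0.11. Members past the threshold over the list alone numbered 9, 9 and 5 without WT mouse 1, 2 or 3, and 13, 11 and 8 without KO mouse 1, 2 or 3; Hsd17b7, Pmvk, Msmo1, Mvd and Lss passed each time. The list means of the KO mice lay at -0.41, -0.33 and -0.91 against -0.04, -0.03 and 0.07 in WT (exact permutation p = 0.1), so KO mouse 3 was the lowest and both others were still below every WT mouse.

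The other SREBP2 targets, genes driven by the sterol-sensing transcription factor outside the pathway itself, fell as well, with a mean of -0.38 over 6 members (camera adjusted p = 9.27e-06). With an estimated correlation the adjusted p was 0.586 (unadjusted p = 0.0236). Rdh11 fell by 0.57 ± 0.17 (SE), Stard4, a sterol carrier, by 0.56 ± 0.14, Insig1, which retains the SREBP precursor, by 0.48 ± 0.18 and Aacs by 0.33 ± 0.12, adjusted over the list alone. Tmem97 and Srebf2 itself, at -0.21 and -0.12, did not pass. With a mouse left out, 4 members passed over the list alone without KO mouse 1, 2 without WT mouse 1, WT mouse 3 or KO mouse 2, and 0 without WT mouse 2 or KO mouse 3.

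**Figure D2:**
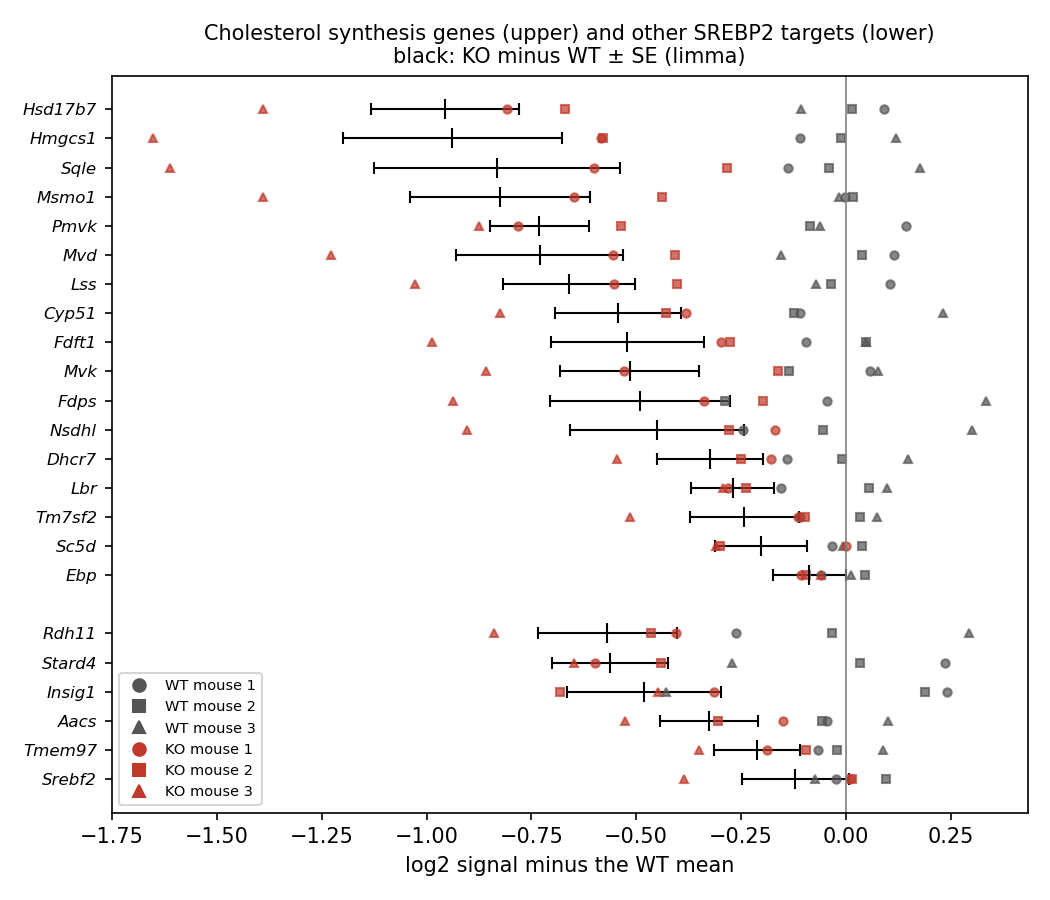
Log2 signal minus the WT mean for the 17 cholesterol synthesis genes (upper block) and the 6 other SREBP2 targets (lower block), with WT mice in grey and KO mice in red, and the KO minus WT difference ± SE in black. All 23 differences are negative, from -0.96 for Hsd17b7 to -0.09 for Ebp, and KO mouse 3 lies lowest for most cholesterol genes.

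The 17 fatty acid synthesis genes tested had a mean of -0.09 (camera adjusted p = 0.0242; adjusted p = 0.586 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. Mlxipl, the carbohydrate-sensing transcription factor ChREBP, was at 0.54 ± 0.13 (SE) and Acss2 at -0.38 ± 0.14 (-0.24 without WT mouse 3), and Srebf1 was at 0.31 ± 0.18 (0.16 without WT mouse 3 or KO mouse 3). Mlxipl passed over the list alone without WT mouse 2, and it is also 1 of the genes within 5 Mb of Gpr146. The list mean was -0.16 without WT mouse 1 or KO mouse 1, both past camera's threshold. It was -0.0015 without KO mouse 2 (adjusted p = 0.443) and -0.03 without WT mouse 2 (adjusted p = 0.209), and quantile normalization also ended the call (adjusted p = 0.0675). Lipoprotein assembly and secretion did not differ by more than the error, at 0.02 over 18 members (adjusted p = 0.933; adjusted p = 0.966 with an estimated correlation). Apoe was at 0.33 ± 0.09 and Sort1, a sorting receptor for lipoproteins, at 0.54 ± 0.17. Over the list alone neither passed with all 6 mice, and both passed without WT mouse 1.

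ERK output and immediate early genes had the largest mean shift of the primary lists, at -0.999 over 19 members, 16 of them negative (camera adjusted p = 7.79e-08; adjusted p = 0.586 with an estimated correlation). Dusp6, a phosphatase induced by ERK activity, fell by 1.00 ± 0.27 (SE) and Ier3 by 0.39 ± 0.09, adjusted over the list alone. Ier3 lay near the filter, at 3.46 in WT and 3.07 in KO, and was at -0.15 with the pseudocount. Its WT values were 3.37, 3.50 and 3.51 in mice 1 to 3, so it was not lowest in WT mouse 3. In the list 12 members had an unadjusted limma p under 0.05 and 0 passed over all genes. Over the list alone 12 members passed without WT mouse 3, Dusp5 and Ier3 without WT mouse 1, and 0 without any of the other 4 mice. The cAMP and CREB list shared the direction, at -0.49 over 9 members (camera adjusted p = 0.00239; adjusted p = 0.586 with an estimated correlation). There Nr4a1, at -2.42 ± 0.68, and Fosb, at -1.01 ± 0.34, did not pass with all 6 mice but did over the list alone without WT mouse 3. These shifts of the list means followed WT mice 1 and 2. The ERK list mean was 0.40 and 0.63 there, and -1.02 in WT mouse 3. In the KO mice it was -0.97, -1.07 and -0.95 (exact permutation p = 0.3). The ERK mean was -1.51 without WT mouse 3 and -0.69 without WT mouse 2, both still past camera's threshold. The cAMP call ended without WT mouse 2 (-0.34, adjusted p = 0.0971) and in the upper 25% of signal (-0.24, adjusted p = 0.216).

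**Figure D3:**
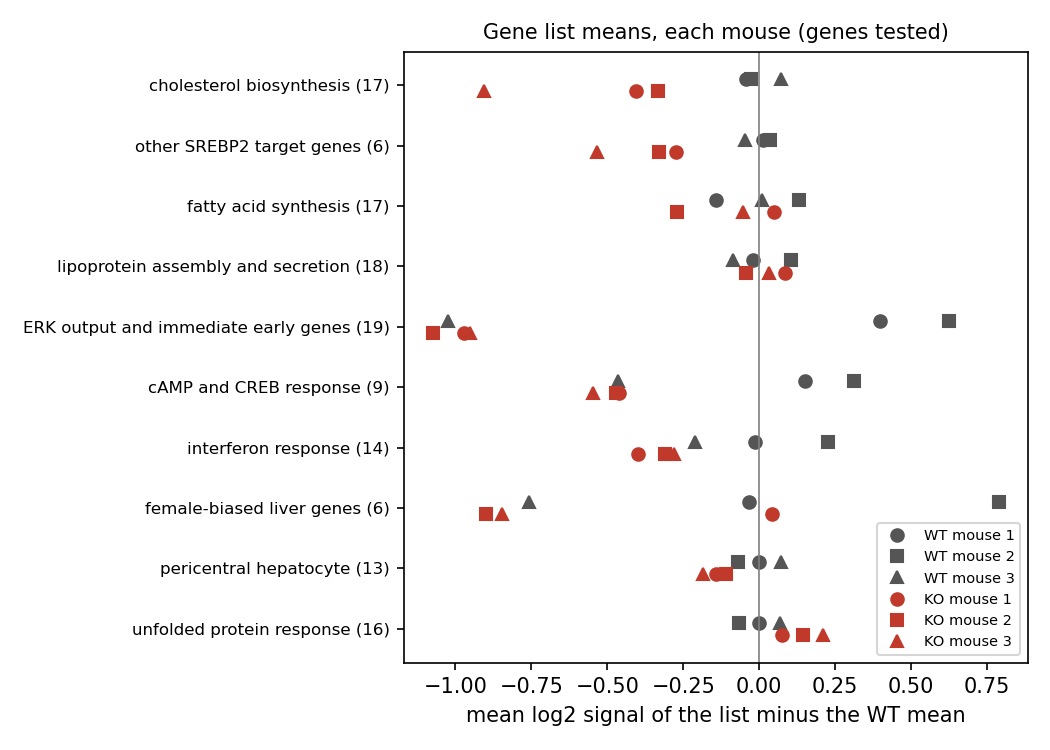
Mean log2 signal of 10 gene lists in each mouse, minus the WT mean, with the number of genes tested in brackets (WT grey, KO red). Both sterol lists separate the genotypes, as do the interferon, pericentral and unfolded protein response lists. For ERK output WT mouse 3 lies at -1.02, among the KO mice.

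Interferon response genes fell in KO, with a mean of -0.33 over 14 members (camera adjusted p = 3.09e-06; adjusted p = 0.586 with an estimated correlation). Igtp, an immunity-related GTPase, fell by 0.82 ± 0.15 (SE) and Ifit1 by 0.80 ± 0.17, adjusted over the list alone; the list mean was 0.23 in WT mouse 2 and -0.21 in WT mouse 3, against -0.28 to -0.40 in KO. The mean was -0.215 without WT mouse 2 and -0.435 without WT mouse 3, both still past camera's threshold; Igtp and Ifit1 passed over the list alone with each mouse left out, and 6 members did without WT mouse 3. Pericentral hepatocyte genes, expressed around the central vein, had a mean of -0.15 over 13 members, 7 of them negative and 6 positive. The camera adjusted p was 0.0242, and 0.586 with an estimated correlation. Rhbg, Oat, ornithine aminotransferase, and Slc1a2, a glutamate transporter, fell by 1.12, 0.60 and 0.34, adjusted over the list alone. The median of the list was -0.02, and Cyp1a2, also a member, was at 0.29. Over the list alone Oat and Rhbg passed with each mouse left out, Slc1a2 only without WT mouse 2. Cyp1a2 passed there, as higher, without KO mouse 1. Camera's call of the list ended without WT mouse 1 (-0.147, adjusted p = 0.0725), WT mouse 3 (-0.11, 0.167) or KO mouse 3 (-0.13, 0.0710). It also ended with quantile normalization (-0.169, 0.0675) or the upper 25% of signal (-0.072, 0.120). Periportal genes had a mean of 0.04 and a median of -0.0036 with camera pointing down (adjusted p = 0.955); Sox9 was at 0.41 ± 0.14 and Cyp2f2 at 0.22 ± 0.14 (0.36 without KO mouse 2, 0.08 without KO mouse 3).

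Female-biased liver genes were lower at -0.57 over 6 members (camera adjusted p = 0.0175; adjusted p = 0.586 with an estimated correlation) with 0 past the threshold over the list alone. Acot3 was at -1.13 ± 0.39 (SE), and passed there without WT mouse 3, and Fmo2 at -0.45 ± 0.25 (-0.22 without WT mouse 2 or KO mouse 3). Their mean was 0.79 in WT mouse 2 and -0.76 in WT mouse 3, against 0.04, -0.90 and -0.85 in KO. The call ended at -0.257 without WT mouse 2 (adjusted p = 0.0856), -0.40 without KO mouse 2 (0.0878), -0.43 without KO mouse 3 (0.0567), -0.61 after quantile normalization (0.0613) and -0.258 with no filter (0.369). The female-biased mean was -0.95 without WT mouse 3 and -0.87 without KO mouse 1. The male-biased list, with Elovl3 at 0.70 and Serpina1e at 0.61 (0.45 and 0.34 without WT mouse 2), had a mean of 0.44 over 14 members (camera adjusted p = 0.147), with WT mouse 2 apart at -0.78. It was 0.05 without WT mouse 2, 0.16 without KO mouse 3, 0.73 without WT mouse 3 and 0.78 without KO mouse 1, and passed without KO mouse 1 (0.000656), WT mouse 3 (0.00513) or WT mouse 1 (0.0391) and with no filter (0.0361). Oxidative phosphorylation, with Atp5o at -0.42 (-0.17 without WT mouse 3) and Uqcrfs1 at -0.17 (-0.11 without KO mouse 2), had a mean of -0.06 over 20 members and passed narrowly (camera adjusted p = 0.0496; adjusted p = 0.586 with an estimated correlation). The call ended in 9 of the 16 alternatives that kept camera's preset correlation, among them leaving out WT mouse 1 (-0.077, 0.0725), WT mouse 3 (-0.025, 0.226), KO mouse 1 (-0.033, 0.175) or KO mouse 2 (-0.042, 0.180). The mean was -0.095 without KO mouse 3.

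The unfolded protein response did not pass as a list, at 0.14 over 16 members (adjusted p = 0.111; 0.0370 without WT mouse 3 and 0.0199 with no filter), but 5 members passed adjusted over the list alone. The endoplasmic reticulum chaperone genes Sdf2l1, Hyou1 and Dnajc3 rose by 0.94 ± 0.25, 0.43 ± 0.14 and 0.39 ± 0.12 (SE), and Dnajb9 fell by 0.56 ± 0.15. Over the list alone 10 members passed without WT mouse 3 and 0 without any of the other 5 mice. Glycolysis and feeding response, at 0.15 with Ppp1r3c at 0.64 and Ppp1r3b at 0.31, had an adjusted p of 0.114, and 0.0361 with no filter. Bile acid synthesis and transport was at 0.19 (adjusted p = 0.375) and 0.092 without WT mouse 2, with Abcb11, the bile salt export pump, at 0.45 ± 0.14 and Nr0b2, the repressor SHP, at 0.72 ± 0.29, or 0.35 without WT mouse 3.

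None of the remaining metabolic lists passed in camera with all 6 mice. Means were 0.02 for LXR targets (adjusted p = 0.929), -0.12 for gluconeogenesis and fasting (0.237), -0.0043 for fatty acid oxidation (0.147), 0.09 for the circadian clock (0.202), -0.08 for the acute phase (0.202), -0.07 for xenobiotic metabolism (0.111) and -0.09 for the cell cycle (0.186). With a mouse left out, 3 of them passed: the acute phase at -0.24 without KO mouse 3 (0.00253), fatty acid oxidation at -0.056 without KO mouse 2 (0.0125) and xenobiotic metabolism at -0.12 without KO mouse 1 (0.0261) or -0.13 without WT mouse 3 (0.0264). The LXR target Abcg8 was at 0.19 (0.12 without KO mouse 3). The fasting genes Igfbp1 and Fbp1 were at -1.41 (-0.71 without WT mouse 2) and -0.16. Slc25a20 and Vnn1 were at -0.23 and -0.27 (Vnn1 at -0.14 without WT mouse 2). The clock output genes Nfil3 and Tef were at 0.34 and 0.31, and the circadian clock mean was 0.13 without WT mouse 2. The acute phase genes Orm3 and Mt1 were at -0.69 and -0.88. Orm3 passed over its list alone without WT mouse 1, and Mt1 did without WT mouse 3. The xenobiotic genes Aldh1a1 and Cyp1a2 were at -0.27 and 0.29. The replication genes Mcm3 and Mcm2 were at -0.34 (-0.21 without WT mouse 2) and -0.24 (-0.13 without KO mouse 3), and the cell cycle mean ran from -0.145 without WT mouse 1 to -0.0094 without WT mouse 2.

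Markers of other cell types gave 1 call among 10 lists with all 6 mice. Among pancreatic acinar genes, Try4 was at -0.51 and Ctrb1 at -0.68 (-0.28 and 0.015 without WT mouse 1). The 3 members tested had a mean of -0.52 (camera adjusted p = 0.0496, and 0.586 with an estimated correlation). Their mean was 0.96 in WT mouse 1 and between -0.70 and -0.41 in the other 5 mice, and the difference was -0.13 without WT mouse 1 (adjusted p = 0.454) and -0.39 without KO mouse 3 (0.0988). Quantile normalization (0.0670) and array weights (0.0707) also ended that call. Kupffer cell genes were at 0.11 (adjusted p = 0.327), sinusoidal endothelial genes at -0.01 (0.410), stellate genes at -0.01 (0.512), bile duct genes at 0.17 (0.419), T and NK genes at -0.02 (0.668), B and plasma genes at -0.01 (0.688), neutrophil and monocyte genes at -0.15 (0.356), erythroid genes at 0.05 (0.933) and fat cell genes at -0.18 (0.105). Without WT mouse 1, Kupffer genes passed at 0.30 (0.000648) and stellate genes at -0.13 (0.0398). Fat cell genes passed at -0.37 without KO mouse 1 (0.00263), -0.32 without WT mouse 3 (0.0171), -0.30 in the upper 25% of signal (0.0347) and -0.20 with the mean of probe sets (0.0380), and were at -0.0097 without KO mouse 2. Bile duct genes were at 0.05 without KO mouse 1 and 0.02 with no filter, and neutrophil and monocyte genes at -0.057 without WT mouse 2, -0.065 without KO mouse 1, -0.092 without KO mouse 3 and -0.012 with no filter. The bile duct, lymphocyte, neutrophil and erythroid lists rest on 1 to 3 genes each. Cd163 and Clec4f of Kupffer cells were at 0.39 and 0.23 (0.12 and 0.08 without KO mouse 3). Dnase1l3 and Kdr of endothelium were at -0.31 and -0.22, with left-out ranges of -0.39 to -0.19 and -0.27 to -0.15. Col3a1 and Col1a2 of stellate cells were at -0.31 and -0.26 (-0.48 to -0.18 and -0.35 to -0.12). Cidec and Pnpla2 of fat cells were at -0.68 and -0.22 (-1.06 to -0.42 and -0.29 to -0.13). Cidec passed over its list alone without KO mouse 1. Krt7, Pkhd1, Ccl5, Prf1, Cd22, Mzb1, Plac8 and Bpgm lay between -0.15 and 0.19.

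Around the targeted gene, 125 genes within 5 Mb were tested. Their mean was 0.04 (camera p = 0.468; p = 0.699 with an estimated correlation), their median 0.0015, and camera pointed down. C130050O18Rik, next to Gpr146 in gene order, was the only one past the threshold adjusted over this list alone. Of the 125, 11 had an unadjusted limma p under 0.05, among them Mlxipl at 0.54. The overlapping gene 3110082I17Rik was at -0.17 ± 0.10 (SE) and Zfand2a, a heat-shock-inducible gene 4 positions away, at -0.61 ± 0.14; these were named after their values were seen.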

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

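Every probe set without a filter, the nearest 50 genes around Gpr146 and the members past the threshold over their list alone with 1 mouse left out were chosen after the data were seen; all other settings were planned. Of 1642 single-gene values under an alternative, 1597 kept their direction and side of the threshold, as did 466 of 571 list values. Most of the single genes had not passed as reported, so this mostly counts values that stayed short of the threshold. Of the 4 genes called, C130050O18Rik kept its call in 15 of 15 alternatives, Map2k6 in 7, Rhbg in 8 and D930048N14Rik in 8. The last 3 account for all 22 lost calls of single genes. Where no cause is given below, the cause was not tested. Counts of genes moved most. The 3 higher and 1 lower genes became 0 and 0 in the upper 25% of signal, a filter that removes all 4 and so says nothing about them, 1 and 0 with the pseudocount, 1 and 0 over every probe set, and 1 to 11 and 0 to 40 with 1 mouse left out. Genes lower numbered 2 after median centring and 3 with trend and robust options. Genes at unadjusted p under 0.05 numbered 1660 with no filter, 567 in the upper 25% and 2922 over every probe set, following the number tested, and 770 to 1026 with 1 mouse left out. Gpr146 was at -1.48 after median centring (adjusted p = 0.0204), -1.47 with trend and robust options (0.0272) and -1.65 to -1.28 with 1 mouse left out, and at -0.97 with the pseudocount (0.0935). The replicate numbers were not taken as pairs in the main fit. Deviations of same-numbered mice correlated at 0.06, -0.19 and 0.15. Not every mouse correlated best with its own number, as WT mouse 2 reached 0.24 with KO mouse 1. With so few mice, these correlations cannot show whether the mice were paired. With the number as a block, 1 gene higher and 0 lower passed, the male-biased list passed (adjusted p = 0.0380) and oxidative phosphorylation did not (0.0623). The primary lists kept their means with an estimated correlation and with fry, at -0.55, -0.38, -0.092 and -0.999, and lost their calls: cholesterol (adjusted p = 0.586 and 0.345), other SREBP2 targets (0.586 and 0.345), fatty acid synthesis (0.586 and 0.820) and ERK output (0.586 and 0.546). With 1 mouse left out, their means ran from -0.66 to -0.37, -0.43 to -0.30, -0.16 to -0.0015 and -1.51 to -0.69. Fatty acid synthesis was at -0.12 after quantile normalization and no longer passed. Some values that had not passed as reported, Ctrb1 through WT mouse 1 and most others near 0, changed sign. The lipoprotein list was at -0.0058 in the upper 25%, -0.00098 after quantile normalization and -0.018 to 0.077 with 1 mouse left out. After quantile normalization the genes near Gpr146 were at -0.0074, LXR targets at -0.0024, and Bpgm and the erythroid list, of which it is the only tested gene, at -0.012. Fatty acid oxidation was at 0.00397 with no filter and 0.012 with array weights, stellate genes at 0.012 with the mean of probe sets, B and plasma genes at 0.037 with no filter, 0.087 with the mean of probe sets and 0.0013 with array weights, and erythroid genes at -0.077 with several-symbol probe sets included. With 1 mouse left out, ranges crossed 0 for LXR targets (-0.024 to 0.094), gluconeogenesis (-0.21 to 0.0036), fatty acid oxidation (-0.056 to 0.048), acute phase (-0.24 to 0.047), xenobiotic metabolism (-0.13 to 0.018), periportal (-0.019 to 0.078), Kupffer (-0.064 to 0.30), endothelial (-0.062 to 0.072), stellate (-0.13 to 0.093), T and NK (-0.077 to 0.013), B and plasma (-0.067 to 0.045) and erythroid genes with Bpgm (-0.046 to 0.13), and for Srebf2 (-0.19 to 0.012), Pkhd1 (-0.0033 to 0.39), Ccl5 (-0.15 to 0.016), Mzb1 (-0.10 to 0.22), Ctrb1 (-1.03 to 0.015) and Alb (-0.024 to 0.00050). Signals near the filter, at 2.99, hold more background, so the pseudocount shrank 36 of 105 single genes by over 1.5 times, among them C130050O18Rik to 1.52, Map2k6 to 0.51, Rhbg to -0.64 and D930048N14Rik to 0.60. With 1 mouse left out, 5, 14 and 10 of the 105 were smaller by over 1.5 times or turned without WT mouse 1, 2 or 3, and 5, 5 and 20 without KO mouse 1, 2 or 3.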

Other observations

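The tests below, other than the splits of the mice for gene counts and secondary lists alone, were chosen after the results were seen, and the rules or scope of 5 of them (refeeding, tried in 3 versions, receptor loss, heat shock, regional change, overlapping gene) were revised after a first run. Other groups of transcripts were looked at after the main tables. Small nucleolar RNA genes had a mean of 0.14 over 68 genes, with 16 higher and 1 lower at unadjusted limma p under 0.05 (camera p = 4.02e-05; p = 0.311 with an estimated correlation); WT mouse 1, at 0.12, lay above KO mouse 1, at -0.03. The 109 microRNA genes tested had a mean of 0.06, with 13 higher and 4 lower at unadjusted limma p under 0.05, and did not pass as a group in camera. Heat shock genes, a list of 14 tested genes picked after the data were seen, had a mean of -0.28 (camera p = 0.00026; p = 0.144 with an estimated correlation) and a median of -0.17, and the mean was -0.17 without Dnajb1; WT mouse 1, at -0.19, lay below KO mouse 3, at -0.16. Among them were Dnajb1 at -1.68, Zfand2a at -0.61 and Hspa8 at -0.25, the 3 of lowest unadjusted limma p; Hspa1b, at -0.59, and Hspa1a, at -0.31, had a higher p. Without WT mouse 3, 9 of the 51 genes called were on the ERK or CREB lists, among them Egr1, Fos and Nr4a1. Over every probe set with no filter 1 passed, and 0 of the 16010 without a listed gene did in limma, where 1408 of them had an unadjusted p under 0.05.

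With 10 splits of the 6 mice into 3 and 3, no share under 0.05 can be reached, so real and highest other values are given side by side. Genes at adjusted p under 0.05 numbered 4 in the real split and at most 0 in the others (1 split as large), and genes at unadjusted p under 0.05 1013 against 826 (1 split). The absolute mean was 0.55 against 0.36 for cholesterol synthesis (1 split), 0.38 against 0.23 for other SREBP2 targets (1 split), 0.09 against 0.22 for fatty acid synthesis (6 splits) and 1.00 against 1.05 for ERK output (3 splits). Lists called numbered 10 against 11 (3 splits) over all 32, 4 against 4 (2 splits) among the primary lists and 6 against 7 (6 splits) among the others, so the preset correlation also calls both primary and other lists between mixed groups.

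Cholesterol synthesis genes were lower in KO livers. A single outlying KO library as the source of the whole shift is argued against, as KO mice 1 and 2 both lay below every WT mouse. The higher of them lay 4.66 SD of the WT mice below the lowest WT mouse. That SD, from 3 mice, was 0.06, against 0.31 in the KO mice. KO mouse 3 adds to the size of the shift, which was -0.37 without it and -0.55 with it. Fewer hepatocytes are argued against, since the lipoprotein genes, also of hepatocytes, did not fall and differed by 0.025. Their list means were 0.09, -0.04 and 0.03 in KO mice 1 to 3 and -0.02, 0.11 and -0.09 in WT. The difference lay above the cholesterol list by 2.74 standard errors. That margin is mostly the cholesterol shift itself and rests on 3 mice per genotype. A weaker refeeding response that includes glycolysis and feeding genes is argued against, as these differed by 0.146, higher in all 3 KO mice than in any WT mouse and 3.51 standard errors above 50% of the cholesterol shift. A weaker response of the lipogenic genes stays open, since fatty acid synthesis alone lay 1.08 standard errors above that level and the 27 genes of both lists, at -0.0035, 1.85, short of the 2 required. The genotype also stays open, with no test of its own here, and the 10 splits are too few to decide on chance.

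C130050O18Rik was higher beside the targeted gene. A regional change reaching many neighbours is argued against. Among 124 other genes within 5 Mb, 10 had an unadjusted limma p under 0.05, 8.06% against 9.13% elsewhere (Fisher's exact odds ratio 0.873, 95% interval 0.406 to 1.67). This share cannot decide on flanking DNA of another strain that spans less than the window or changes few genes. Cross-signal from the overlapping gene 3110082I17Rik is argued against, since it was not higher, at -0.17 ± 0.10 (SE). Altered transcripts of the Gpr146 locus, which its own probes may not read, stay a candidate explanation that was not tested. So do a local effect of the targeted allele on this 1 gene, and strain variants acting on it alone or on few genes.

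Immediate early genes were lower in KO livers through WT mice 1 and 2. Loss of the receptor as the only cause stays open: 1 of 3 WT mice lay within the KO range, and 1 mouse is too few to exclude it. A heat shock response in WT mice 1 and 2 stays open too. The heat shock mean was -0.19 in WT mouse 1, 0.02 in WT mouse 2 and 0.17 in WT mouse 3, against the direction it needs. WT mouse 1 minus WT mouse 3 was -0.35 ± 0.19, an SE over genes that does not measure the spread between mice. With 1 mouse against 1 mouse, the comparison cannot decide. The order and timing of dissection, which could move such genes within minutes, were not tested and are not given in the sources used here.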
